A study of Felis catus with 24 samples.

How the data were processed

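RNA from the mesenteric lymph nodes of 24 cats was sequenced, with 1 library per cat. The labels place 10 cats in a group with feline infectious peritonitis (FIP). The other 14 had no FIP, and the labels divide them into 8 without feline coronavirus (FCoV) in the node and 6 with it. Each cat was taken from its own title, but in the FIP group the descriptions give other numbers. The FIP ages, and so the log2 age covariate and the choice of cats aged at most 4 years, rest on the titles. With 1 library per cat, edgeR and permutation p-values measure the spread between cats. Those of list tests with a preset correlation mainly measure the spread between genes. Per the labels, RNA was extracted with an RNeasy kit, treated with ezDNase to remove DNA, and made into stranded libraries of polyadenylated RNA with a TruSeq kit.

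The deposited count tables hold 1 whole number per gene and library, with no normalization by the authors. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic, STAR 2.7.1, featureCounts and edgeR. The order and roles of these tools, the genome build, annotation and strand setting of the counting are not given in the sources used here. How reads shared between near-identical or overlapping genes were treated is therefore not known. Immunoglobulin genes are many and alike, and only a summed share of counts in annotated genes is reported for them.

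The authors also deposited 4 tables of their own comparisons. Per the file headers, these give a log2 ratio, a p-value and an adjusted p-value (a fraction between 0 and 1) for each listed gene, with its symbol, its coordinates and its Gene Ontology terms. The listed genes are a selection: the largest p-value in the authors' table of FIP and non-FIP cats was 0.04978, and the smallest absolute log2 ratio was 0.5006. In all 4 tables, 100 percent of joined genes had the opposite sign to the fold change computed here (first named group over the other). In 3 tables this is what their names say, since FIP or FCoV-positive cats are the denominator. The authors' table named as FIP over non-FIP instead holds ratios of non-FIP over FIP. Its log2 ratio for CXCL10 was -4.149, against 4.16 here, and the correlation across its 3900 joined genes was -0.983. Genes are not independent replicates, so this correlation describes only the sign and the scale. All fold changes given for FIP cats here are FIP over the other group.

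The count tables hold 19493 gene identifiers. Gene symbols were taken only from the authors' comparison tables, which name 4469 genes, of which 4438 passed the filter on low counts. The RefSeq gene table at hand, for assembly F.catus_Fca126_mat1.0, matched 0 of the identifiers and supplied no names. Named genes are therefore genes that the authors had listed as differing between these same samples. Counts of changed members in a gene list are not independent evidence of its direction. Coordinates are from the authors' tables, on a build not given.

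Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM-scaled library sizes and robust quasi-likelihood models. The filter filterByExpr on the 3 groups kept 13791 genes. FIP and non-FIP cats were compared in a model of 2 groups. The 3 comparisons between pairs of groups came from 1 model of 24 libraries with a mean per group, so that the groups share 1 estimate of the spread. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 13791 genes. A gene was called changed at an adjusted p under 0.05. Standard errors were obtained from the fold change and the F statistic. Levels are CPM with TMM factors, as mean ± SD, and log2 CPM used a prior count of 2. The median log2 fold change over all genes was -0.079, -0.091, -0.034 and -0.052 in the 4 comparisons.

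Before the data were examined, 31 gene lists (782 genes) of pathways and cell type markers were fixed, and 369 of those genes had a symbol. They cover pattern recognition receptors, type I interferon-stimulated genes, interferon-gamma and Th1 genes, inflammatory cytokines, chemokines, monocytes and macrophages, neutrophils, T cells, B cells, germinal centres, plasma cells, cytotoxic and NK cells, regulatory T cells and checkpoints, dendritic cells, fibroblasts and matrix, endothelium, adipocytes, intestinal epithelium, mesothelium, erythroid cells and platelets, proliferation, apoptosis, complement, class I antigen presentation, coronavirus entry, Th2 and Th17 cells, eosinophils and mast cells, glycolysis and hypoxia, immediate early and heat shock genes, mitochondrial-encoded genes and ribosomal proteins. Each of the 24 lists with at least 5 named members was tested with camera (limma 3.58.1) against the other named genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. Camera p-values were adjusted over the lists of a comparison. A list score per library is the mean log2 CPM of the named members, each centred on its mean over the 24 libraries.

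The rule for naming genes was fixed at the same time. It takes the 5 largest rises and the 5 largest falls among called genes with a symbol and an average log2 CPM of at least 1. It adds up to 4 members of each described list in order of p, and a fixed set of 24 immune genes. IL10, CD68, CD79A, JCHAIN, MKI67 and ANPEP belong to that set but had no symbol in the tables and are not analysed here. Some other genes that the rule takes are not reported here, and no genes were put in their place. All 31 lists are described for FIP against non-FIP. For the other 3 comparisons, the lists with named members were picked after the list results had been seen. Genes outside the rule are named only where that is stated.

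The authors' tables give 35 genes the Gene Ontology function of immunoglobulin receptor binding. These are called immunoglobulin-annotated genes here, and immunoglobulin genes without that term or outside the tables are not among them. The share of counts in the 35 genes and 7 list scores were compared between groups by two-sided permutation tests. These were exact with under 10 cats in a group and otherwise used 100000 resamples. The p-values of these 32 tests were adjusted together. The genes behind the share and the scores had been listed by the authors as differing between these same samples. Permutation p-values of shares and scores can therefore be too small.

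Library totals fell into 2 separate classes that the labels do not mention: 9 shallower libraries with 4298359 to 7250790 counts and 15 deeper libraries with 12800054 to 36090892. Each class holds cats of all 3 groups. The 32 permutation tests were repeated within each class.

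The alternatives chosen beforehand were RLE size factors in place of TMM, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 6 libraries, the replicate number as a block, log2 age as a covariate, only cats aged at most 4 years, omission of the 3 cats with blood cell neoplasia, FIP against the mean of the 2 non-FIP groups, only the 2 groups compared, and omission of each library in turn. Added after the data had been seen were depth class as a covariate, each depth class alone, omission of 3 libraries with an adipocyte score above 3, omission of the immunoglobulin-annotated genes, and the 2 age alternatives with the ages of the FIP cats taken by the number in the description. A list of 26 exocrine pancreas genes was also written after pancreatic genes had been seen among the largest falls.

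The steps were tested on simulated data, with 200 of the 13791 genes changed by known folds at the real depths and spread. For FIP against non-FIP, 11.9 percent of genes changed 1.5-fold, 49.3 percent of those changed 2-fold and 84.8 percent of those changed 4-fold were recovered, with 7 false calls among 104. For FCoV-positive against FCoV-negative cats the shares were 5.97, 26.9 and 69.7 percent. For FIP against FCoV-negative cats they were 4.48, 35.8 and 81.8 percent, and against FCoV-positive cats 5.97, 23.9 and 72.7 percent. In each simulated comparison the 1 changed list was called, and 0 of 20 unchanged lists were called by camera with the preset correlation. The simulated genes varied independently of one another. The simulation therefore does not test the preset correlation on real lists, where for interferon-stimulated genes of FIP against non-FIP the estimated correlation was 0.63.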

Results

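Feline infectious peritonitis (FIP) is a systemic inflammatory disease that develops in some cats infected with feline coronavirus (FCoV). Messenger RNA was measured in the mesenteric lymph node, which drains the intestine, in 10 cats with FIP, 8 cats without FIP or FCoV in the node, and 6 cats without FIP but with FCoV in the node. Infection was natural, and the labels give each of the 14 non-FIP cats another disease or condition, among them pneumonia, enteropathy and pleural effusion. Among these, 3 FCoV-positive cats (numbers 2, 3 and 4) had lymphoma or round cell neoplasia. The groups also differed in age, with a median of 1.5 years in FIP, 8 years in FCoV-negative and 9 years in FCoV-positive cats. Breeds were not balanced either: most cats of both non-FIP groups were labelled DSH, and most FIP cats were of other breeds. Breed was not tested as an explanation. The age of 1 FCoV-negative cat was not known.

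Library totals ranged from 4548394 to 36090892 counts in FIP, from 4389912 to 24087408 in FCoV-negative and from 4298359 to 27919844 in FCoV-positive cats. The 9 shallower libraries, none above 7250790 counts, were cats 1, 2 and 3 of both non-FIP groups and FIP cats 1, 3 and 4. Between 14476 and 16118 genes were detected per library. No pair of libraries held identical counts, and the highest correlation of log2 CPM between any pair was 0.97. The first principal component took 25.7 percent of the variance and the next 17.4 percent.

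The comparison of FIP with non-FIP cats addressed how the node differs in cats that have developed the disease. In tests of gene lists with camera, genes of the antiviral interferon response, pattern recognition receptors, inflammatory cytokines, myeloid markers and plasma cell markers were higher as lists in FIP nodes, and markers of T cells and B cells were lower. These calls hold with a preset correlation between genes, and with an estimated one 0 of 24 lists passed. The interferon-stimulated gene ISG15 reached 1060 ± 555 CPM (SD, n = 10) in FIP and 66.5 ± 65.2 CPM (n = 14) in non-FIP cats. The chemokine CXCL10 reached 428 ± 278 against 24 ± 14.2 CPM. The T cell receptor component CD3E stood at 113 ± 44.6 against 245 ± 110 CPM. Of 13791 genes, 1642 rose and 1674 fell (edgeR, adjusted p under 0.05), and 889 of the rises and 877 of the falls were at least 2-fold. The authors' deposited table lists 2968 genes at an adjusted p under 0.05 for these groups, and 2904 of them were called here.

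The largest rise was that of CSF3, the growth factor G-CSF that drives neutrophil production (ENSFCAG00000014992, chromosome E1, 40999548 to 41001163). Its log2 fold change was 5.97 ± 0.85 (SE, adjusted p = 1.83e-05), from 0.129 ± 0.161 CPM to 7.87 ± 11.8 CPM. CCL7, a monocyte-attracting chemokine (ENSFCAG00000013588, chromosome E1, 21536721 to 21538176), rose by 5.58 ± 0.84 on the log2 scale (adjusted p = 3.69e-05). Complement component C5 (ENSFCAG00000000645, chromosome D4, 82081683 to 82170504) rose by 5.5 ± 0.54 (adjusted p = 9.48e-08), from 1.36 ± 1.62 to 58.5 ± 39.4 CPM. CLEC5A, a myeloid lectin receptor (ENSFCAG00000008023, chromosome A2, 156350353 to 156358230), rose by 5.29 ± 0.66 (adjusted p = 2.55e-06). ACOD1, the itaconate-producing enzyme of activated macrophages (ENSFCAG00000010436, chromosome A1, 50324867 to 50329215), rose by 5.26 ± 0.89 (adjusted p = 0.000141), from 4.94 ± 10.4 to 195 ± 158 CPM.

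Of the 5 largest falls, 4 had their high values in 1 or a few non-FIP libraries. CYP1A1, a xenobiotic-metabolising cytochrome (ENSFCAG00000002016, chromosome B3, 33532067 to 33538470), changed by -9.83 ± 2.04 (adjusted p = 0.00111), with 552 CPM in FCoV-negative cat 1 and 54.5 CPM in FCoV-negative cat 5. Without cat 1 its log2 fold change was -6.82. The pancreatic enzyme genes CELA1 (ENSFCAG00000004411, chromosome B4, 80456829 to 80473710) and CPA1 (ENSFCAG00000014234, chromosome A2, 146576190 to 146582964) changed by -6.21 ± 1.44 (adjusted p = 0.00286) and -5.97 ± 1.62 (adjusted p = 0.00907). FCoV-positive cat 6 held 898 CPM of CELA1 and 1190 CPM of CPA1. Without it the values were -3.14 for CELA1 and -3.05 for CPA1, and the call of CPA1 was lost. FRMPD1, a scaffold protein gene (ENSFCAG00000011920, chromosome D4, 61381005 to 61431466), changed by -5.90 ± 1.07 (adjusted p = 0.000302). KLHL31 (ENSFCAG00000014353, chromosome B2, 53805108 to 53808697) changed by -5.46 ± 1.29 (adjusted p = 0.00321), and by -2.90 without FCoV-negative cat 1, which held 58.6 CPM. With limma-voom none of these 5 falls passed the threshold, while all 5 of the largest rises did.

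**Figure D1:**
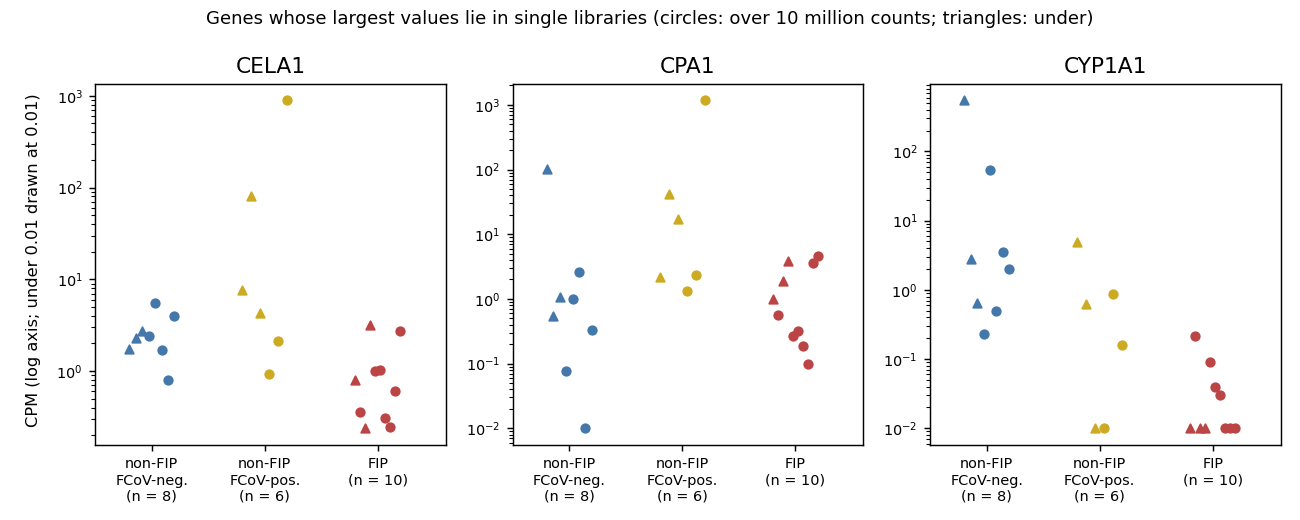
CPM of CELA1, CPA1 and CYP1A1 in each of 24 libraries on log axes, with values under 0.01 drawn at 0.01, circles for the 15 deeper libraries and triangles for the 9 shallower ones. The highest points are FCoV-positive cat 6 for CELA1 (898 CPM) and CPA1 (1190 CPM) and FCoV-negative cat 1 for CYP1A1 (552 CPM).

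Type I interferon-stimulated genes, the antiviral effectors induced by interferon, rose in FIP in 26 of 27 named members (27 adjusted over the list alone). Their median log2 fold change was 2.40 (camera adjusted p = 2.1e-22, adjusted p = 0.093 with an estimated correlation). HERC5, an enzyme that attaches ISG15 to proteins, rose by 2.49 ± 0.21 (adjusted p = 1.68e-08). IFIT3 rose by 4.74 ± 0.46, HERC6 by 3.16 ± 0.31 and RTP4 by 2.11 ± 0.21. MX1 rose by 3.12 ± 0.34 and ISG15 by 4.00 ± 0.48 (adjusted p = 3.46e-07 and 1.54e-06). The list score was 1.61 ± 0.76 (SD, n = 10) in FIP and -1.15 ± 0.70 (n = 14) in non-FIP cats, a difference of 2.76. Its permutation p was 1e-05, the smallest 100000 resamples can give, and the adjusted p over 32 tests was 0.00016. Within the depth classes the difference was 3.30 in the 9 shallower libraries (exact permutation p = 0.012) and 2.58 in the 15 deeper ones (exact permutation p = 0.00016).

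Pattern recognition receptors, which sense microbial molecules, rose in 12 of 15 members and fell in 2 (13 and 2 adjusted over the list alone; median 1.99, camera adjusted p = 1.7e-06, adjusted p = 0.093 with an estimated correlation). The RNA sensor DDX58 rose by 2.83 ± 0.27, TLR2 by 2.72 ± 0.28, CLEC4E by 3.70 ± 0.42, TLR4 by 1.99 ± 0.24 and TLR8 by 1.29 ± 0.25. Interferon-gamma and Th1 genes rose in 10 of 16 members and fell in 3 (11 and 3 adjusted over the list alone; median 1.34, camera adjusted p = 0.00021, adjusted p = 0.24 with an estimated correlation). CXCL10, CXCL11 and CXCL9 rose by 4.16 ± 0.39, 4.60 ± 0.50 and 3.82 ± 0.42, and the tryptophan-degrading enzyme IDO1 by 2.59 ± 0.30. IFNG rose by 3.09 ± 0.54 (adjusted p = 0.000185), from 0.765 ± 0.704 to 6.73 ± 5.71 CPM. Inflammatory cytokines rose in 12 of 15 members and fell in 2 (12 and 2 adjusted over the list alone; median 1.37, camera adjusted p = 0.0022, adjusted p = 0.21 with an estimated correlation). The B cell survival factor TNFSF13B rose by 1.83 ± 0.19, IL1B by 2.84 ± 0.36, the interleukin-1 antagonist IL1RN by 4.18 ± 0.57 and IL6 by 3.20 ± 0.72. TNF rose by 0.96 ± 0.32 (adjusted p = 0.0301), a call lost without FIP cat 1, 4 or 5, with a lowest value of 0.83. Chemokines rose in 7 of 13 members and fell in 4 (8 and 4 adjusted over the list alone), with CCL2 up by 3.27 ± 0.44, CCL8 by 4.95 ± 0.68 and CCL13 by 2.76 ± 0.53. As a list they did not pass (camera adjusted p = 0.064, and 0.34 with an estimated correlation).

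**Figure D2:**
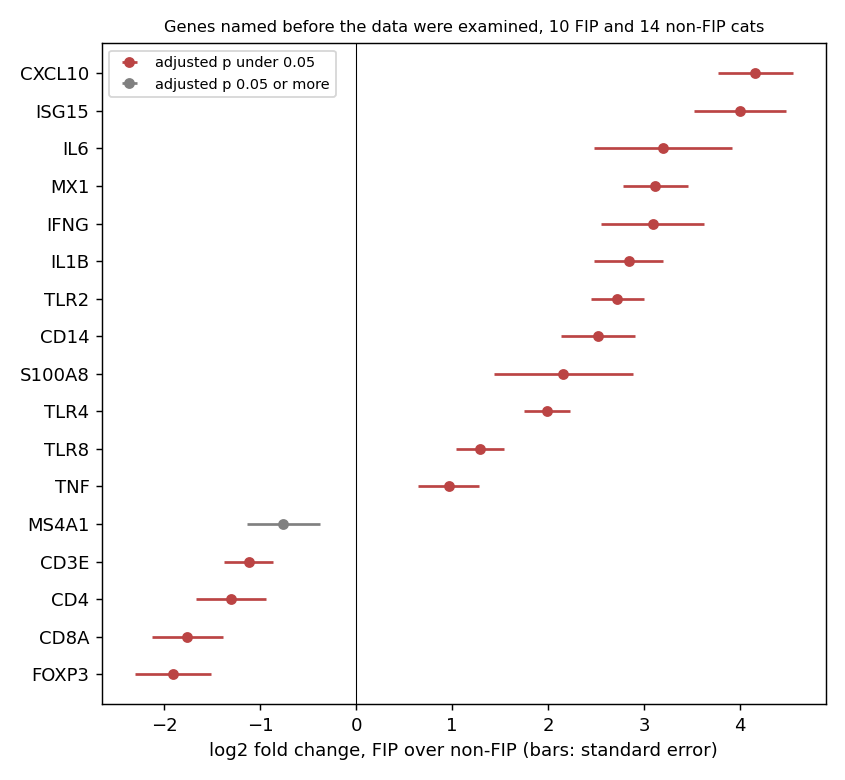
Log2 fold change of FIP over non-FIP (10 and 14 cats) for genes of the fixed immune set, with standard errors as bars and genes past an adjusted p of 0.05 in red. CXCL10 lies highest at 4.16, FOXP3 lowest at -1.91, and MS4A1 (grey, -0.76) did not pass.

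Monocyte and macrophage markers rose in 11 of 22 members and fell in 2 (13 and 3 adjusted over the list alone; median 1.02, camera adjusted p = 0.0045, adjusted p = 0.40 with an estimated correlation). The endotoxin co-receptor CD14 rose by 2.52 ± 0.39, SLC11A1 by 3.70 ± 0.60, ADGRE1 by 2.95 ± 0.57 and the sialic acid receptor SIGLEC1 by 1.88 ± 0.39. Neutrophil markers rose in 10 of 15 members and fell in 1, likewise adjusted over the list alone (median 1.60, camera adjusted p = 0.023, adjusted p = 0.46 with an estimated correlation). The decoy receptor IL1R2 rose by 3.13 ± 0.58, TREM1 by 2.20 ± 0.54 and the chemokine receptor CXCR2 by 2.12 ± 0.57. MPO, the myeloperoxidase of neutrophil granules, changed the other way, by -2.71 ± 0.64. S100A8 rose by 2.16 ± 0.72 (adjusted p = 0.0306), a call lost without FIP cat 3, 4 or 8 (lowest 1.97). Without FCoV-negative cat 1 it was 3.32 and the neutrophil median 2.54. Without the 3 cats with neoplasia the calls of S100A8 (1.90, adjusted p = 0.0675) and of the neutrophil list (median 1.43, adjusted p = 0.092) were lost, with fold changes about as large. The neutrophil score differed by 1.84 between the groups (permutation p = 0.00042, adjusted p = 0.0013), by 2.40 in the shallower libraries (exact permutation p = 0.071) and by 1.67 in the deeper ones (exact permutation p = 0.00093).

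Complement genes rose in 8 of 17 members and fell in 1 (13 and 1 adjusted over the list alone; median 1.30, camera adjusted p = 8.8e-05, adjusted p = 0.093 with an estimated correlation). Beside C5 the rises included the C1 inhibitor SERPING1 (1.77 ± 0.17) and the C1 proteases C1S (1.63 ± 0.18) and C1R (1.60 ± 0.18). Apoptosis genes rose in 13 of 15 members and fell in 2, likewise adjusted over the list alone (median 0.77, camera adjusted p = 0.00043, adjusted p = 0.093 with an estimated correlation). The strongest was CASP1, the inflammasome protease (1.69 ± 0.16), followed by the survival genes BCL2L1 (1.00 ± 0.14) and CFLAR (0.98 ± 0.15). The risen members thus include inhibitors of cell death. Class I antigen presentation genes rose in 9 of 10 members (10 adjusted over the list alone; median 0.82, camera adjusted p = 0.00025, adjusted p = 0.18 with an estimated correlation), among them PSMB9 (1.41 ± 0.13), TAP1 (1.45 ± 0.21), TAPBP (1.13 ± 0.20) and PSME2 (0.80 ± 0.17). Regulatory T cell and checkpoint genes rose in 6 of 10 members and fell in 1 (6 and 2 adjusted over the list alone; median 1.08, camera adjusted p = 0.034, adjusted p = 0.24 with an estimated correlation). The rises included CD80 (2.59 ± 0.28), CD274 (2.54 ± 0.33) and CD86 (1.56 ± 0.25), ligands that antigen-presenting cells carry, and VSIR (0.88 ± 0.18). The list call was lost with the age covariate (median 0.856, adjusted p = 0.068) and in cats aged at most 4 years (1.15, adjusted p = 0.078), with medians about as large. FOXP3, the regulator that defines regulatory T cells, fell by 1.91 ± 0.40 (adjusted p = 0.00119).

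T cell markers fell in 22 of 23 members (23 adjusted over the list alone; median -1.39, camera adjusted p = 2.5e-06, adjusted p = 0.34 with an estimated correlation). UBASH3A, a regulator of T cell receptor signalling, changed by -1.88 ± 0.32 (adjusted p = 0.000158), CD27 by -1.94 ± 0.37, the kinase LCK by -1.52 ± 0.31 and its adaptor LAT by -1.68 ± 0.35. CD3E changed by -1.12 ± 0.26, CD4 by -1.31 ± 0.37 and CD8A by -1.76 ± 0.37 (adjusted p = 0.00261, 0.0105 and 0.00133). The T cell score differed by -1.32 (permutation p = 0.00096, adjusted p = 0.0024), by -1.79 in the shallower libraries (exact permutation p = 0.048) and by -1.11 in the deeper ones (exact permutation p = 0.019). B cell markers fell in 12 of 16 members (14 adjusted over the list alone; median -1.25, camera adjusted p = 0.00095, adjusted p = 0.35 with an estimated correlation). CD72 changed by -2.40 ± 0.45, FCER2 by -2.25 ± 0.48 and BLK by -1.81 ± 0.41. MS4A1, which encodes CD20, did not pass (-0.76 ± 0.38, adjusted p = 0.147). The B cell score differed by -1.18 (permutation p = 0.0025, adjusted p = 0.0047), by -1.72 in the shallower libraries (exact permutation p = 0.048) and by -0.92 in the deeper ones (exact permutation p = 0.043). Th2 and Th17 genes had 4 named members, too few for a list test. CCR4 (-2.23 ± 0.41), CCR6 (-1.78 ± 0.45) and GATA3 (-1.13 ± 0.29) fell, and the interleukin-33 receptor IL1RL1 rose (3.51 ± 0.77).

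Several lymphoid lists did not pass as lists. Germinal centre genes fell in 4 of 10 members and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.064, and 0.51 with an estimated correlation). SH2D1A changed by -1.56 ± 0.31, MYBL1 by -2.56 ± 0.54, ELL3 by -2.67 ± 0.56 and LMO2 by -0.87 ± 0.25. Cytotoxic and NK cell genes fell in 8 of 16 members and rose in 3 (8 and 4 adjusted over the list alone; camera adjusted p = 0.14, and 0.57 with an estimated correlation). Granzyme gene GZMK changed by -3.81 ± 0.59, from 86.2 ± 150 to 6.05 ± 2.85 CPM, EOMES by -2.40 ± 0.43 and CTSW by -2.03 ± 0.38, while the death ligand TNFSF10 rose by 1.80 ± 0.32. Dendritic cell markers rose in 3 of 11 members and fell in 3 (3 and 4 adjusted over the list alone; camera adjusted p = 0.70, and 0.78 with an estimated correlation). IDO1, CADM1 (0.86 ± 0.23) and TCF4 (0.77 ± 0.25) rose, and the lipid antigen receptor CD1C changed by -3.18 ± 0.94.

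Plasma cell markers rose in 15 of 19 members (16 adjusted over the list alone; median 1.32, camera adjusted p = 6e-05, adjusted p = 0.34 with an estimated correlation). The surface marker SDC1 rose by 1.97 ± 0.33 (adjusted p = 0.000107), the secretory pathway genes FKBP11 and TXNDC5 by 2.01 ± 0.42 and 2.11 ± 0.47, and CD38 by 1.63 ± 0.37. The plasma cell score differed by 1.62 (permutation p = 6e-05, adjusted p = 0.00037), by 1.71 in the shallower libraries (exact permutation p = 0.048) and by 1.59 in the deeper ones (exact permutation p = 0.00062). The 35 immunoglobulin-annotated genes took 19.7 ± 9.04 percent of all counts in FIP (SD, n = 10) and 4.24 ± 4.39 percent in non-FIP cats (n = 14). The permutation p of this difference was 1e-05, the smallest the test can give (adjusted p = 0.00016). It can be too small, since the 35 genes were listed from these same samples. In the shallower libraries the shares were 23.2 and 5.79 percent (exact permutation p = 0.036), and in the deeper ones 18.2 and 3.07 percent (exact permutation p = 0.00016). FIP cat 4 was lowest in its group at 4.74 percent, and FCoV-positive cat 3 was highest among non-FIP cats at 16.1 percent.

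**Figure D3:**
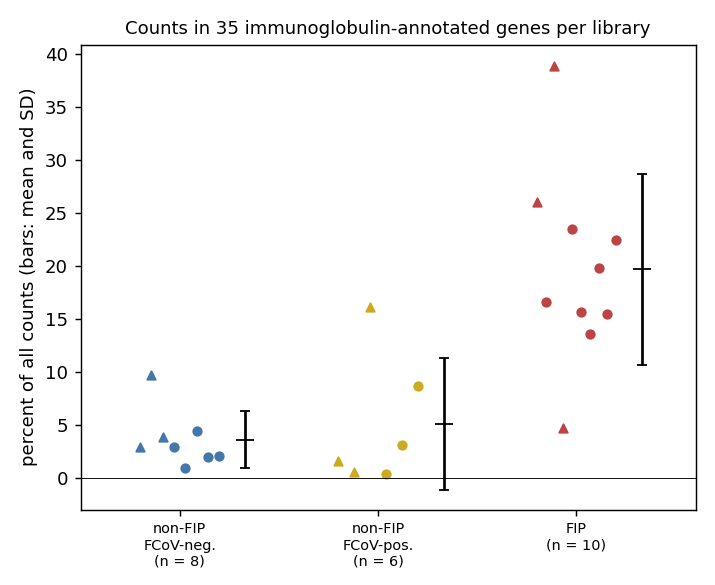
Percent of each library's counts in 35 immunoglobulin-annotated genes, with 1 point per cat (circles for the 15 deeper libraries, triangles for the 9 shallower ones) and black bars for the group mean and SD. FIP cats average 19.7 percent, FCoV-negative 3.61 percent and FCoV-positive 5.08 percent, and the ranges overlap through FIP cat 4 (4.74 percent) and FCoV-positive cat 3 (16.1 percent).

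**Figure D4:**
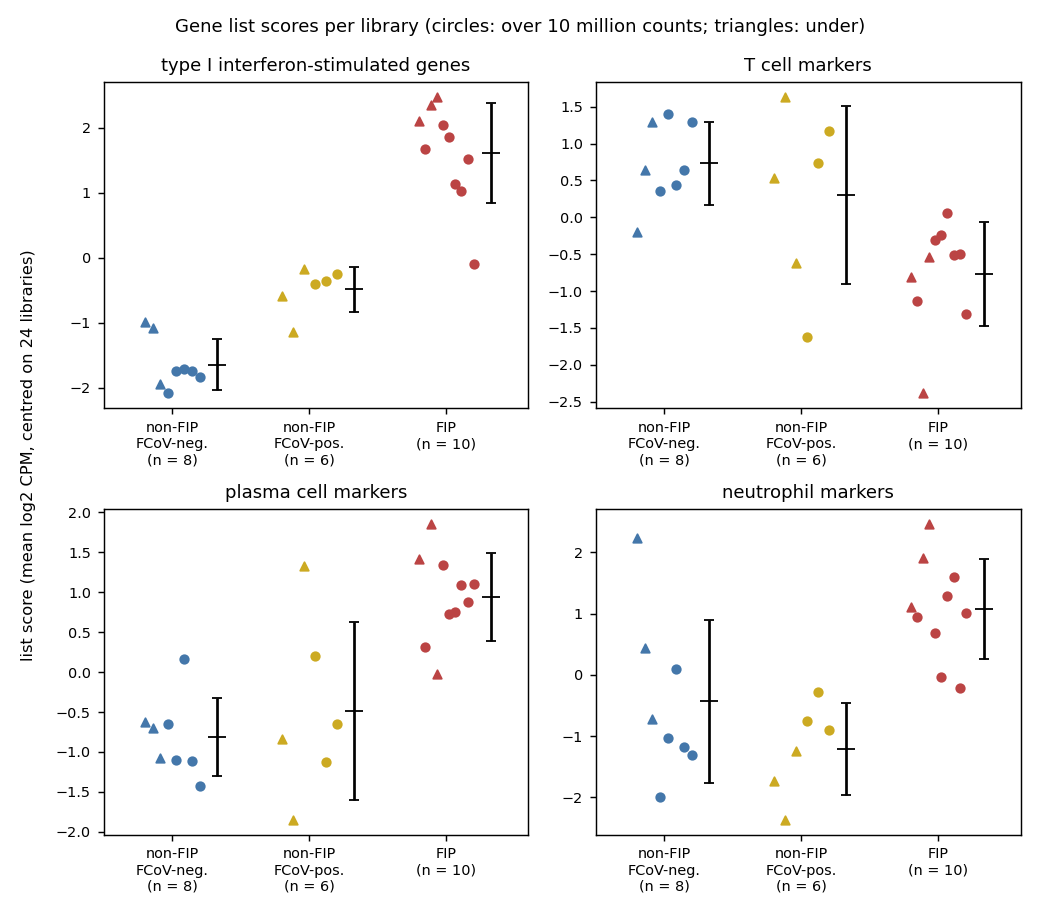
List scores per library (mean log2 CPM of the named members, centred on the 24 libraries) for interferon-stimulated genes and T cell, plasma cell and neutrophil markers, with black bars for the group mean and SD, circles for the 15 deeper libraries and triangles for the 9 shallower ones. Interferon scores average 1.61 in FIP, -0.49 in FCoV-positive and -1.65 in FCoV-negative cats, while T cell scores average -0.77 in FIP.

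Lists of tissue that can be dissected along with a node also differed. Adipocyte markers fell in 12 of 14 members (14 adjusted over the list alone; median -3.65, camera adjusted p = 0.021, adjusted p = 0.56 with an estimated correlation). CIDEA, a lipid droplet protein, changed by -5.30 ± 1.01, DGAT2 by -4.05 ± 0.92, ADRB3 by -3.19 ± 0.77 and the lipase LIPE by -3.06 ± 0.83. The adipocyte score differed by -1.98 (permutation p = 0.021, adjusted p = 0.032), by -2.67 in the shallower libraries (exact permutation p = 0.13) and by -1.34 in the deeper ones (exact permutation p = 0.15). FCoV-negative cat 1 had the highest score, 6.13, and without it the list median was -2.13, DGAT2 -2.65 and LIPE -1.86. Without the 3 libraries with a score above 3 (FCoV-negative cat 1 and FCoV-positive cats 3 and 6) the list median was -0.779 and its call was lost (adjusted p = 0.075). It was also lost with the age covariate and FIP ages by description number (-1.62, adjusted p = 0.055). Mesothelial markers, of the lining of the abdominal cavity, rose in 6 of 6 members (likewise adjusted over the list alone; median 2.89, camera adjusted p = 0.047, adjusted p = 0.46 with an estimated correlation). UPK3B rose by 3.59 ± 0.84, KRT19 by 3.01 ± 0.81, WT1 by 2.13 ± 0.57 and LRRN4 by 3.26 ± 0.89. This list call was lost in 11 of the 24 fits that each omit 1 library (medians 2.51 to 3.46). It was also lost with the age covariate (median 2.97, adjusted p = 0.11), with the depth class as a covariate (2.94, adjusted p = 0.052), without the 3 cats with neoplasia (2.7, adjusted p = 0.08) and without the immunoglobulin-annotated genes (2.9, adjusted p = 0.052), where the medians stayed about as large, and in the deeper libraries alone (1.95, adjusted p = 0.093). The mesothelial score differed by 2.58 (permutation p = 0.0013, adjusted p = 0.0028), by 3.78 in the shallower libraries (exact permutation p = 0.024) and by 2.02 in the deeper ones (exact permutation p = 0.042). Intestinal epithelial markers had 4 named members, with KRT19 up, CLDN4 down (-3.90 ± 1.15), and PIGR (-1.62 ± 0.71) and CLDN7 (1.47 ± 0.68) not passing. CLDN4 lost its call without FCoV-negative cat 1 (-1.52).

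Fibroblast and matrix genes rose in 9 of 21 members (11 adjusted over the list alone; median 1.20, camera adjusted p = 0.0017, adjusted p = 0.46 with an estimated correlation). With the age covariate the median was 0.613 (adjusted p = 0.027). PDPN rose by 2.65 ± 0.38, the protease MMP14 by 1.22 ± 0.25, fibronectin FN1 by 2.10 ± 0.45 and PDGFRA by 1.20 ± 0.26. Endothelial markers rose in 5 of 11 members and fell in 2, likewise adjusted over the list alone (camera adjusted p = 0.38, and 0.59 with an estimated correlation). The adhesion molecules ICAM1 (1.11 ± 0.19) and PECAM1 (0.73 ± 0.17) rose, and the scavenger receptors STAB2 (-2.33 ± 0.60) and STAB1 (-1.55 ± 0.40) fell. The only named member of the erythroid and platelet list, TREML1, fell (-2.09 ± 0.57). Of 3 eosinophil and mast cell members, IL5RA fell (-1.55 ± 0.52, adjusted p = 0.0306), a call lost without any 1 of FCoV-positive cat 4 and FIP cats 5, 7, 8 and 9 (-1.13 to -1.67 over all 24 omissions) and without the 3 cats with neoplasia (-1.16, adjusted p = 0.0747), and KIT (-0.86 ± 0.39) and CMA1 (-1.10 ± 0.57) did not pass.

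Ribosomal protein genes had a median of -0.46 (camera adjusted p = 0.016, adjusted p = 0.57 with an estimated correlation), but 0 of 20 members passed over all genes or over the list alone with edgeR, RPL14 being nearest (-0.63 ± 0.24, adjusted p = 0.0547). RPL23 (-0.64 ± 0.24), RPS4X (-0.72 ± 0.30) and RPL5 (-0.58 ± 0.25) followed, and these 4 genes passed with DESeq2 and with limma-voom. The list median was -0.75 without FIP cat 10, and with the age covariate it was -0.305 and the list call was lost (adjusted p = 0.083). Glycolysis and hypoxia genes rose in 5 of 11 members (6 up and 2 down adjusted over the list alone; camera adjusted p = 0.22, and 0.51 with an estimated correlation), including the glucose transporter SLC2A1 (0.92 ± 0.19) and PFKFB4 (0.69 ± 0.20). VEGFA (0.99 ± 0.36) and HK2 (1.07 ± 0.39) passed narrowly and lost their calls in 17 and 15 of the 24 fits with 1 library omitted (0.87 to 1.28 and 0.85 to 1.34). Immediate early and heat shock genes, which mark handling stress among other stimuli, rose in 3 of 12 members and fell in 2 (6 and 3 adjusted over the list alone; camera adjusted p = 0.29, and 0.57 with an estimated correlation). ATF3 rose by 2.93 ± 0.31, DUSP1 by 1.24 ± 0.25 and EGR2 by 1.04 ± 0.35, and DUSP2 changed by -0.96 ± 0.30. EGR2 lost its call without any 1 of FCoV-positive cat 2 and FIP cats 1, 3, 4 and 6 (0.96 to 1.23 over all 24 omissions). Of 4 proliferation genes, MCM7 fell (-0.54 ± 0.18, adjusted p = 0.0306), a call lost without FIP cat 1 or 2 (-0.44 to -0.64) and without the 3 cats with neoplasia (-0.467, adjusted p = 0.0703), and MCM6 (-0.83 ± 0.39), TK1 (-0.86 ± 0.40) and BIRC5 (-0.57 ± 0.27) did not pass. Of the genes on the coronavirus entry list, the protease CTSB (1.67 ± 0.31), LY6E (1.07 ± 0.24) and NRP1 (1.00 ± 0.27) rose. The list was not divided into genes that aid entry and genes that restrict it. The only named mitochondrial-encoded gene, CYTB, did not pass with edgeR (-0.66 ± 0.25, adjusted p = 0.0582).

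Of the 24 lists tested, 17 passed camera with the preset correlation and 0 with an estimated one. Their members are genes listed from these same samples, so the member counts, medians and list tests are not independent evidence. The count of 3316 called genes was 2102 with log2 age as a covariate, and 1186 and 1253 within the shallower and the deeper libraries alone. Of the 118 named genes called, 17 lost their call with limma-voom, 22 with the age covariate, 51 in the 9 shallower libraries and 34 in the 15 deeper ones.

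The comparison of FIP with FCoV-negative cats addressed the disease against nodes without the virus. Every one of the 27 named interferon-stimulated genes rose, over all genes as over the list alone (median 2.89, camera adjusted p = 5.7e-30, adjusted p = 0.068 with an estimated correlation). HERC5 rose by 2.87 ± 0.22 (adjusted p = 4.9e-09), ISG15 by 5.31 ± 0.47, the RNA-degradation trigger OAS1 by 4.09 ± 0.37 and IFIT3 by 5.64 ± 0.52. ISG15 stood at 1060 ± 555 CPM (SD, n = 10) in FIP and 26.9 ± 15.5 CPM (n = 8) in FCoV-negative cats. The antiviral gene RSAD2 (chromosome A3, 137737238 to 137753371) went from 1.27 ± 0.82 to 114 ± 87.4 CPM. With edgeR 1401 genes rose and 1438 fell, and the authors' deposited table lists 2541 genes at an adjusted p under 0.05, of which 2403 were called here.

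The largest rises over FCoV-negative cats were CSF3 (8.17 ± 1.20, adjusted p = 4.85e-05), ACOD1 (7.50 ± 1.09), the chemokine CCL8 (6.72 ± 0.77, chromosome E1, 21573359 to 21574851), RSAD2 (6.51 ± 0.65) and CCL7 (6.51 ± 1.12). CCL7 was 9.87 without FCoV-negative cat 6. The largest falls were CYP1A1 (-10.6 ± 1.70, adjusted p = 0.000137), KLHL31 (-6.07 ± 1.30), FRMPD1 (-6.06 ± 1.13), CIDEA (-5.63 ± 1.06, chromosome D3, 34114051 to 34123942) and APOL6 (-5.32 ± 1.40, chromosome B4, 132103384 to 132104196). Without FCoV-negative cat 1, KLHL31 was -1.09 and APOL6 0.14, neither of them called, CIDEA was -2.37 and CYP1A1 -7.57.

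Against FCoV-negative cats T cell markers fell in 21 of 23 members (22 adjusted over the list alone; median -1.46, camera adjusted p = 6.5e-07, adjusted p = 0.30 with an estimated correlation), with UBASH3A at -1.83 ± 0.35, CD27 at -1.85 ± 0.40, LCK at -1.54 ± 0.35 and CD3E at -1.23 ± 0.29. B cell markers fell in 11 of 16 members and rose in 1 (15 and 1 adjusted over the list alone; median -1.35, camera adjusted p = 0.00041, adjusted p = 0.30 with an estimated correlation). CD72 changed by -2.40 ± 0.50, FCER2 by -2.29 ± 0.52, BLK by -1.95 ± 0.46 and the B cell identity factor PAX5 by -1.94 ± 0.46. Plasma cell markers rose in 17 of 19 members (19 adjusted over the list alone; median 1.57, camera adjusted p = 2.2e-05, adjusted p = 0.30 with an estimated correlation), with SDC1 up by 2.12 ± 0.40, SLAMF7 by 1.45 ± 0.32, TXNDC5 by 2.59 ± 0.57 and CRELD2 by 2.50 ± 0.56. Fibroblast and matrix genes rose in 12 of 21 members (15 adjusted over the list alone; median 1.39, camera adjusted p = 0.00041, adjusted p = 0.38 with an estimated correlation), including PDPN (2.90 ± 0.47), the gelatinase MMP2 (2.76 ± 0.60), COL6A3 (1.68 ± 0.38) and MMP14 (1.34 ± 0.30). Mesothelial markers rose in 6 of 6 members (likewise over the list alone; median 4.5, camera adjusted p = 0.018, adjusted p = 0.35 with an estimated correlation). LRRN4 rose by 5.48 ± 1.17, UPK1B by 5.14 ± 1.13, UPK3B by 5.01 ± 1.13 and WT1 by 3.04 ± 0.69, and UPK3B was 9.44 without FCoV-negative cat 1. The mesothelial score was 1.51 ± 1.87 in 10 FIP cats and -1.75 ± 0.985 in 8 FCoV-negative cats (exact permutation p = 0.00094, adjusted p = 0.0024), with differences of 3.88 in the shallower libraries (exact permutation p = 0.2) and 3.07 in the deeper ones (exact permutation p = 0.0076). Neutrophil markers rose in 4 of 15 members and fell in 1 (likewise over the list alone; median 1.33) and did not pass as a list (camera adjusted p = 0.11, and 0.54 with an estimated correlation). Their score differed by 1.51 (exact permutation p = 0.011, adjusted p = 0.018), by 1.18 in the shallower libraries (exact permutation p = 0.3) and by 1.84 in the deeper ones (exact permutation p = 0.0051). Ribosomal protein genes fell in 7 of 20 members (13 adjusted over the list alone; median -0.69, camera adjusted p = 0.00041, adjusted p = 0.49 with an estimated correlation).

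Of the 24 lists, 16 passed camera with the preset correlation and 0 with an estimated one. The count of 2839 genes was 1751 with the age covariate, 532 in the shallower libraries alone and 2159 in the deeper ones alone. With limma-voom, 4 of the 34 named genes lost their call (APOL6, KLHL31, LRRN4 and UPK1B), as did 23 in the shallower libraries and 4 in the deeper ones. The symbols come from genes listed on these same samples, so the list counts are not independent evidence here either.

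The comparison of FIP with FCoV-positive cats addressed the disease against nodes that carried the virus without FIP. Interferon-stimulated genes rose in 25 of 27 members, likewise over the list alone (median 1.93, camera adjusted p = 4.2e-17, adjusted p = 0.12 with an estimated correlation), and neutrophil markers rose in 8 of 15 (11 up and 1 down adjusted over the list alone; median 2.38, camera adjusted p = 0.0021, adjusted p = 0.39 with an estimated correlation). The neutrophil median was 4.16 in the shallower libraries and 1.34 in the deeper ones. HERC5 rose by 2.11 ± 0.24 (adjusted p = 1.44e-05), IFIT3 by 4.04 ± 0.54, IFIT2 by 3.39 ± 0.48 and HERC6 by 2.69 ± 0.38. Among neutrophil genes IL1R2 rose by 3.51 ± 0.83, the alarmins S100A12 and S100A8 by 3.85 ± 0.96 and 3.91 ± 0.99, and TREM1 by 2.91 ± 0.75, and all 4 calls were lost without the 3 cats with neoplasia, where the values stayed about as large (IL1R2 3.75, S100A12 3.67, S100A8 3.78 and TREM1 3.12). S100A8 stood at 76.9 ± 55.8 CPM (SD, n = 10) in FIP and 4.91 ± 3.96 CPM (n = 6) in FCoV-positive cats. With edgeR 873 genes rose and 777 fell, and the authors' deposited table lists 1857 genes at an adjusted p under 0.05, of which 1451 were called here.

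The largest rises over FCoV-positive cats were CLEC5A (5.58 ± 0.98, adjusted p = 0.000749), CSF3 (4.98 ± 1.05), CCL7 (4.87 ± 1.13), C5 (4.87 ± 0.72) and the fatty acid receptor GPR84 (4.61 ± 0.69, chromosome B4, 83091745 to 83092929). CCL7 was 8.49 without FCoV-positive cat 4. Of the 5 largest falls, 4 encode pancreatic enzymes or zymogen granule proteins: CELA1 (-7.41 ± 1.10, adjusted p = 0.00016), CPA1 (-7.07 ± 1.60), the lipase CEL (-6.22 ± 1.21, chromosome D4, 92561898 to 92569783) and SYCN (-5.40 ± 1.09, chromosome E2, 14326629 to 14327880). FRMPD1 changed by -5.63 ± 1.14. Without FCoV-positive cat 6 the values were -4.24 for CELA1, -3.0 for CPA1, -2.61 for CEL and -2.76 for SYCN, and only CELA1 of these kept its call.

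Mesothelial markers did not pass against FCoV-positive cats. Of 6 members 0 passed, over all genes as over the list alone (median 2.03, camera adjusted p = 0.16, and 0.52 with an estimated correlation). Their score differed by 1.68 (exact permutation p = 0.081, adjusted p = 0.1), by 3.68 in the shallower libraries (exact permutation p = 0.1) and by only 0.264 in the deeper ones (exact permutation p = 0.81).

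T cell markers fell against FCoV-positive cats in 13 of 23 members (16 adjusted over the list alone; median -1.23, camera adjusted p = 5.6e-05, adjusted p = 0.44 with an estimated correlation), with UBASH3A at -1.93 ± 0.37, CD27 at -2.06 ± 0.43, CD8A at -1.98 ± 0.43 and LAT at -1.84 ± 0.41. B cell markers fell in 3 of 16 members (12 adjusted over the list alone; median -1.16, camera adjusted p = 0.005, adjusted p = 0.45 with an estimated correlation), namely CD72 (-2.40 ± 0.52), FCER2 (-2.19 ± 0.55) and BLK (-1.61 ± 0.48). FCER2 lost its call without FCoV-positive cat 1 (-1.62), and BLK without any 1 of FCoV-positive cats 1, 2, 3 and 6 and FIP cat 1 (-1.47 to -1.85). Cytotoxic and NK cell genes fell in 6 of 16 members and rose in 2 (10 and 2 adjusted over the list alone; median -1.12, camera adjusted p = 0.029, adjusted p = 0.47 with an estimated correlation), with GZMK at -4.46 ± 0.60, EOMES at -2.79 ± 0.47, CTSW at -2.46 ± 0.42 and TNFSF10 at 1.77 ± 0.44. Without FCoV-positive cat 5 the list median was -0.615 and its call was lost, as it was without FIP cat 10, and GZMK was -2.77. Adipocyte markers fell in 3 of 14 members (10 adjusted over the list alone; median -2.87, camera adjusted p = 0.00095, adjusted p = 0.45 with an estimated correlation), CIDEA (-4.68 ± 1.05), DGAT2 (-3.41 ± 0.97) and ADRB3 (-2.87 ± 0.88), with LIPE at -2.75 ± 0.92 (adjusted p = 0.051). DGAT2 lost its call without FCoV-positive cat 6 (-2.98), and ADRB3 without any 1 of FCoV-positive cats 1, 2 and 3 and FIP cats 2, 3, 7 and 8 (-2.36 to -3.13). Without the 3 cats with neoplasia DGAT2 (-3.73, adjusted p = 0.0516), ADRB3 (-2.21, adjusted p = 0.216) and TNFSF10 (1.71, adjusted p = 0.0978) lost their calls. Without the 3 libraries with high fat RNA the adipocyte median was -1.8 and still called. The adipocyte score was -1.15 ± 1.25 in FIP and 1.93 ± 1.16 in FCoV-positive cats (exact permutation p = 0.0005, adjusted p = 0.0015), with differences of -2.99 in the shallower libraries (exact permutation p = 0.1) and -2.97 in the deeper ones (exact permutation p = 0.025). The T cell and B cell scores differed by -1.07 and -0.94 between these groups and did not pass (exact permutation p = 0.04 and 0.046, adjusted p = 0.056 and 0.061). In the shallower libraries these differences were -1.76 and -1.85 (exact permutation p = 0.2 and 0.1), and in the deeper ones only -0.66 and -0.31 (exact permutation p = 0.3 and 0.57).

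Of the 24 lists, 15 passed camera with the preset correlation and 0 with an estimated one. The count of 1650 genes was 752 with the age covariate, 940 without the 3 cats with neoplasia, 340 in the shallower and 149 in the deeper libraries alone. With limma-voom, 11 of the 32 named genes called lost their call, among them CSF3, CELA1, CPA1, CEL, SYCN and FRMPD1, as did 20 in the shallower and 17 in the deeper libraries. The B cell list lost its call in the deeper libraries (median -0.653), and the cytotoxic list in the shallower ones (-0.771) and in cats aged at most 4 years (-0.442). Omitting FCoV-positive cat 2 gave 827 genes, cat 1 1021 and cat 6 1052. The list counts again rest on genes listed from these same samples.

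The comparison of FCoV-positive with FCoV-negative cats addressed what the virus in the node goes with when FIP has not developed. No gene passed in edgeR, but type I interferon-stimulated genes were higher as a group in FCoV-positive nodes. The median log2 fold change of the 27 named members was 0.96 (camera adjusted p = 2.5e-22, adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 22 of the 27 passed and all 22 were higher, against 0 over all genes. ISG15 stood at 119 ± 69.7 CPM (SD, n = 6) in FCoV-positive and 26.9 ± 15.5 CPM (n = 8) in FCoV-negative cats, a log2 fold change of 2.15 ± 0.43 (edgeR adjusted p = 0.102, the smallest of all genes). OAS1 followed with 1.51 ± 0.36 (adjusted p = 0.273), at 62.0 ± 23.9 against 21.8 ± 11.7 CPM, then IFI35 with 0.88 ± 0.23 and DHX58 with 1.21 ± 0.33. The list score was -0.49 ± 0.35 (SD, n = 6) in FCoV-positive and -1.65 ± 0.39 (n = 8) in FCoV-negative cats (difference 1.16, exact permutation p = 0.0013, adjusted p = 0.0028). In the shallower libraries the difference was 0.705 (exact permutation p = 0.3, where 3 against 3 cats cannot go below 0.1), and in the deeper ones 1.49 (exact permutation p = 0.018). The list median was 0.55 in cats aged at most 4 years and 0.56 in the shallower libraries alone, both past camera's threshold.

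Over all genes edgeR called 0, with 827 genes at an unadjusted p under 0.05 where 690 would be expected by chance. DESeq2 called 40 genes and limma-voom 0. The authors' deposited table lists 1 gene at an adjusted p under 0.05, which was not called here. Omission of FCoV-negative cat 1 gave 29 genes, of FCoV-positive cat 2 gave 4 and of FCoV-positive cat 4 gave 1, and ISG15 passed without FCoV-negative cat 1 or FCoV-positive cat 2 and OAS1 without FCoV-negative cat 1.

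In 8 further lists the camera test of FCoV-positive against FCoV-negative cats passed with the preset correlation although 0 members passed edgeR over all genes. Interferon-gamma and Th1 genes had a median of 0.45 (camera adjusted p = 0.014, adjusted p = 0.60 with an estimated correlation, 0 of 16 passing over the list alone), with IL27 at 1.52 ± 0.47, IL12RB1 at 0.88 ± 0.33, EBI3 at 0.57 ± 0.33 and IRF1 at 0.37 ± 0.25. Its call was lost without FCoV-negative cat 1, and also in cats aged at most 4 years (median 0.0569, adjusted p = 0.67), in the deeper libraries (0.293, adjusted p = 0.46) and without the 3 libraries with high fat RNA (0.206, adjusted p = 0.38). Cytotoxic and NK cell genes had a median of 0.80 (camera adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation, 4 of 16 passing over the list alone), with the pore-forming PRF1 at 1.63 ± 0.46, NKG7 at 1.11 ± 0.39, CCL5 at 1.54 ± 0.54 and GZMH at 1.35 ± 0.50. Without FCoV-positive cat 5 this median was 0.053 and not called, NKG7 was 0.687, CCL5 0.31 and GZMH 0.676. The call was also lost without FCoV-negative cat 1, 3 or 4, in the shallower libraries (0.243, adjusted p = 0.2), in the deeper ones (1.28, adjusted p = 0.084) and without the 3 libraries with high fat RNA (0.879, adjusted p = 0.2). In cats aged at most 4 years it was -0.188. Mesothelial markers had a median of 1.95 (camera adjusted p = 0.0034, adjusted p = 0.60 with an estimated correlation, 2 of 6 passing over the list alone), with UPK1B at 3.37 ± 1.13, LRRN4 at 3.17 ± 1.17, WT1 at 1.58 ± 0.71 and UPK3B at 2.21 ± 1.14. Without FCoV-negative cat 1 the median was 2.96, UPK3B 6.64 (adjusted p = 0.0204) and WT1 2.23, and WT1 was 0.878 without FCoV-positive cat 4. UPK3B was 1.48 without FCoV-positive cat 5. In cats aged at most 4 years the median was 0.682 and not called. The mesothelial score differed by 0.195 in the shallower libraries (exact permutation p = 0.9) and by 2.80 in the deeper ones (exact permutation p = 0.018).

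Neutrophil markers had a median of -1.18 (camera adjusted p = 0.0034, adjusted p = 0.60 with an estimated correlation, 0 of 15 passing over the list alone), with LTF at -3.61 ± 1.37, S100A12 at -2.37 ± 0.91, S100A8 at -2.37 ± 0.94 and PGLYRP1 at -2.61 ± 1.04. Without FCoV-negative cat 1 the median was -0.35 and not called, LTF was -0.349, S100A12 -1.35, S100A8 -0.954 and PGLYRP1 -0.494. Without the 3 libraries with high fat RNA the median was -0.398 and not called. The neutrophil score differed by -2.43 in the shallower libraries (exact permutation p = 0.1, the smallest that 3 against 3 cats allow) and by 0.44 in the deeper ones (exact permutation p = 0.38), so the direction did not hold within both classes. Ribosomal protein genes had a median of -0.61 (camera adjusted p = 4.9e-10, adjusted p = 0.60 with an estimated correlation, 0 of 20 passing over the list alone), with RPL22 at -0.68 ± 0.30, RPL5 at -0.66 ± 0.30, RPL23 at -0.65 ± 0.30 and RPS6 at -0.66 ± 0.30. In the shallower libraries the ribosomal median was -0.283 and the call was lost (adjusted p = 0.23).

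T cell markers of FCoV-positive over FCoV-negative cats had a median of -0.096 (camera adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation, 0 of 23 passing over the list alone), which ranged from -0.36 to 0.063 with 1 library omitted and lost its call without FCoV-negative cat 3, 5 or 8 or FCoV-positive cat 3 or 4. It was -0.291 in the deeper libraries and 0.139 in the shallower ones. Germinal centre genes had a median of -0.56 (camera adjusted p = 0.014, adjusted p = 0.63 with an estimated correlation, 0 of 10 passing over the list alone), which was -0.27 and not called without FCoV-negative cat 4 and also lost its call without FCoV-positive cat 4. Without the 3 cats with neoplasia the germinal centre median was -0.108 (adjusted p = 0.63). It was -1.02 in the deeper libraries (adjusted p = 0.00017) but 0.531 in the shallower ones, where the list was called in the opposite direction (adjusted p = 0.018). Fibroblast and matrix genes had a median of 0.60 (camera adjusted p = 0.015, adjusted p = 0.73 with an estimated correlation, 0 of 21 passing over the list alone), which was 0.15 and not called without FCoV-positive cat 4 and also lost its call without FCoV-negative cat 3 or FCoV-positive cat 1 and in cats aged at most 4 years (0.548, adjusted p = 0.28). The fibroblast median was 1.3 in the deeper libraries (adjusted p = 0.00087) and -0.218 in the shallower ones (adjusted p = 0.62). For adipocyte markers the median was -0.94 while camera gave the upward direction without passing (adjusted p = 0.12, and 0.81 with an estimated correlation). The immunoglobulin share was 5.08 ± 6.20 percent in FCoV-positive and 3.61 ± 2.69 percent in FCoV-negative cats (exact permutation p = 0.59), with differences of 0.596 percentage points in the shallower libraries (exact permutation p = 1) and 1.60 in the deeper ones (exact permutation p = 0.54).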

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

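The tests of pancreas RNA, fat, neoplasia, depth class, single libraries, immunoglobulin transcripts and cell shares, of age behind the interferon and T cell lists, and of chance behind the genes at an unadjusted p under 0.05, were chosen only after the results had been seen.

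Chance was tested by assigning the same cats to groups of the same sizes, with 100 splits drawn per comparison, the real one included. For FIP against non-FIP cats, 1 of the 100 splits gave as many genes as the real one (3316), namely the real one, and the highest other split gave 31. Against FCoV-negative cats it was 1 of 100, with 2839 real calls and 1642 in the highest other split, which kept 9 of the 10 FIP cats together. Against FCoV-positive cats it was 1 of 100, with 1650 real calls and 103 in the highest other split. A chance assignment of cats is thus excluded for these 3 counts. For FCoV-positive against FCoV-negative cats, where edgeR called 0 genes (827 at an unadjusted p under 0.05, 40 by DESeq2, 0 by limma-voom), all 100 of the splits gave as many, as they must beside a real count of 0, so this count tests nothing. Of the same splits, 45 gave at least 827 genes at an unadjusted p under 0.05, and a chance assignment is not excluded. Of the other 99 splits, 9 called any gene and 4 more than 5, with a median of 0 and a highest of 106. A split with that many calls may reflect a structure among these cats, which was not tested.

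Age differs between the groups, so the log2 age slope within the 13 non-FIP cats of known age was used to predict each called change of FIP against non-FIP. The median ratio of predicted to observed change was -0.0758, between -0.121 and -0.0373 with each of those cats omitted, against about 1 if age were the cause. This argues against age as the cause of most of the 3316 calls. It does not cover effects of age that appear only in young or only in sick cats.

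Among 165 groups of 6 to 10 values, 18 held a value far from the rest by Dixon's test at the 95 percent level, where chance gives about 8. FIP cat 10 was lowest of the FIP cats in log2 CPM of ACOD1 (1.69, others 6.24 to 8.98), C5 (0.861, others 4.28 to 7.12) and MX1 (7.34, others 9.63 to 10.7). FCoV-negative cat 1 was highest of its group in the adipocyte score (6.13, others -2.62 to 0.685), the glycolysis and hypoxia score (0.858, others -0.685 to -0.235), the mesothelial score (0.471, others -2.57 to -1.34) and log2 CPM of CPA1 (6.71, others -2.92 to 1.47) and KLHL31 (5.88, others -2.92 to -0.213). The same cat was lowest in the dendritic cell score (-0.771, others 0.0011 to 0.661).

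FCoV-negative cat 2 was highest of its group in the share of counts in the 10 top genes (13.2 percent, others 7.97 to 10.3) and in immunoglobulin-annotated genes (9.69 percent, others 0.969 to 4.45). FCoV-negative cat 3 was lowest in log2 CPM of TLR4 (3.21, others 4.45 to 5.43) and TLR8 (4.04, others 4.77 to 5.39). CCL7 was highest in FCoV-negative cat 6 (0.325, others -2.92 to -1.79) and in FCoV-positive cat 4 (1.62, others -2.92 to -1.91). FCoV-positive cat 4, a cat with neoplasia, was lowest of its group in log2 CPM of MS4A1 (3.69, others 7.04 to 8.4) and in the regulatory T cell and checkpoint score (-0.692, others -0.0385 to 0.273). FCoV-positive cat 2 was lowest in log2 CPM of MX1 (6.2, others 7.37 to 8.07).

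Pancreatic enzyme genes and adipocyte markers were among the largest falls in FIP, and a candidate explanation is tissue sampled along with a few non-FIP nodes. For pancreas, 7 of 26 listed exocrine genes had a symbol, and their values were highest in FCoV-positive cat 6 (CPA1 at 1190 and CEL at 1060 CPM), a library looked at because of these genes. The difference in mean score between FIP and FCoV-positive cats went from -2.11 (exact permutation p = 0.01) to -1.08 without it (exact permutation p = 0.029 over 3003 splits), which argues against pancreas RNA in cat 6 alone. The falls of CPA1, CEL and SYCN lost their calls without it (-3.0, -2.61 and -2.76), while CELA1 kept its call (-4.24). FCoV-positive cat 2 held 81.2 CPM of CELA1, 52 of CEL and 41.7 of CPA1, where the highest FIP values were 3.14, 8.53 and 4.61 CPM, so pancreas RNA in more than 1 library stays open. For fat, the adipocyte list median went from -3.65 to -0.779 without the 3 libraries of highest score (adjusted p = 0.075, and from 0.00053 to 0.075 over its alternatives), and the difference in mean score went from -1.98 to -1.04 (permutation p = 0.09). These libraries were chosen for their scores, so their omission could only shrink the difference, and what is left of this difference neither excludes fat in those 3 alone nor shows it. Against FCoV-negative cats alone the score differed by -1.15 with all libraries (exact permutation p = 0.26). Against FCoV-positive cats it differed by -3.08 (exact permutation p = 0.0005) and by -2.39 without the 3 libraries (exact permutation p = 0.004 over 1001 splits), and the list median went from -2.87 to -1.8 and stayed called (adjusted p = 0.0001), which argues against fat in those 3 libraries alone for this comparison. Smaller amounts of fat in other nodes and a loss of fat in FIP cats stay open as well, and no biological explanation was tested.

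Interferon-stimulated genes were higher in FCoV-positive than in FCoV-negative nodes, with a difference in mean score of 1.16. Without the 3 cats with neoplasia it was 1.25 (exact permutation p = 0.0061 over 165 splits), within the depth classes it averaged 1.1 (exact permutation p = 0.0027 over 1120 splits within the classes), and the list median of 0.964 did not go below 0.911 when any 1 library was omitted. With log2 age beside the group the score difference was 1.13 ± 0.207 (SE, 13 cats of known age, p = 0.00028). These values argue against neoplasia, depth, single libraries and age as the cause. An interferon response to virus in the node may underlie the difference, a hypothesis found on these same 14 cats and not tested here, since no virus amount per node was at hand. Their other diseases stay open as an untested explanation, and the list did not pass with an estimated correlation between genes.

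T cell markers were lower in FIP nodes. Their list median was -1.39, and -1.75 in the cats aged at most 4 years (camera adjusted p = 1.2e-08; adjusted p from 1.2e-08 to 3.1e-05 over all its alternatives with the preset correlation, and 0.34 with an estimated one). With FIP ages by description number the median at these ages was -1.74. No non-FIP cat of known age was under 1 year old, while the FIP group holds cats of 4 to 10 months. These medians thus cannot separate FIP from an age under 1 year. The counts left outside the 35 immunoglobulin-annotated genes differed by a mean log2 share of -0.261 (-0.289 to -0.218 with 1 library omitted). This is the shift that counts taken up by these genes would give every other gene before scaling by TMM factors. Immunoglobulin genes outside the 35 are not covered. The medians argue against the cats over 4 years among the non-FIP cats as the cause, while an effect of an age under 1 year stays open. The share argues against counts taken up by these 35 genes as the cause of most of the fall. A lower share of lymphocytes alone would raise other cell types alike. Score differences over 6 such lists ran from -0.344 for dendritic cells to 2.58 for mesothelium. Their range was 2.93 after centring within each library (permutation p = 0.00086). But their members were listed from these same samples and mesothelium can be dissected along with a node, so the range cannot decide this. A growth of single cell populations, such as those behind the monocyte (1.29) and neutrophil (1.84) markers, a loss of T cells and lower transcription per T cell may each contribute and stay open, since bulk RNA holds no cell numbers.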

How the results depend on the processing

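Depth class as a covariate, each depth class alone, omission of the 3 libraries with high fat RNA, omission of immunoglobulin-annotated genes and the ages of the FIP cats by description number were chosen after the results had been seen. The cause of the changes below was not tested, except that omissions and single depth classes leave fewer cats.

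For FIP against non-FIP cats the 3316 called genes became 2102 with log2 age as a covariate, 1186 in the shallower libraries alone and 1253 in the deeper ones. Against FCoV-negative cats 2839 became 1751 with the age covariate and 532 in the shallower libraries. Against FCoV-positive cats 1650 became 752 with the age covariate, 940 without the 3 cats with neoplasia, 340 in the shallower and 149 in the deeper libraries. Between FCoV-positive and FCoV-negative cats, 0 with edgeR (827 at an unadjusted p under 0.05) became 40 with DESeq2, 5 without a filter on low counts, 1 with the age covariate, 7 without the cats with neoplasia, 1 with only the 2 groups compared and 60 in the deeper libraries, and was 0 with limma-voom. With FIP ages by description number, counts against FCoV-positive cats were 882 with the age covariate and 2498 in cats aged at most 4 years. Under the other alternatives, the omission of single libraries apart, these 4 counts stayed within 1.5 times their value. With the replicate number as a block, although the cats differ and 20 pairs with the same number correlated between -0.24 and 0.34, the counts were 3534, 2913, 1424 and 0.

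The camera tests called 17, 16, 15 and 9 lists with the preset correlation and 0, 0, 0 and 0 with an estimated one.

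With each library omitted in turn the counts ran from 2858 (without FIP cat 1) to 3853 (FIP cat 10), from 2300 (FCoV-negative cat 5) to 3645 (FCoV-negative cat 1), from 827 (FCoV-positive cat 2) to 2090 (FCoV-positive cat 4), and from 0 to 29 (FCoV-negative cat 1). Called lists ran from 16 to 18, 15 to 17, 14 to 16 and 6 to 12.

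List medians of FIP against non-FIP cats that moved over 1.5 times were those of fibroblast genes (1.20, and 0.613 with the age covariate), cytokines (1.37, and 0.885 in the deeper libraries), monocytes (1.02, and 1.7 in cats aged at most 4 years), neutrophils (1.60, 2.98 in cats aged at most 4 years and 2.58 without the 3 libraries with high fat RNA), mesothelium (2.89, 4.7 in cats aged at most 4 years and 4.48 in the shallower libraries), ribosomal proteins (-0.46, from -0.928 to -0.304) and adipocytes (-3.65, up to -0.779). Against FCoV-negative cats they included fibroblast genes (1.39, and 2.14 in cats aged at most 4 years) and ribosomal proteins (-0.69, and -1.13 in those cats). Against FCoV-positive cats they included neutrophils (2.38, from 1.34 to 4.16), T cells (-1.23, and -1.86 in the shallower libraries), B cells (-1.16, from -1.79 to -0.653), cytotoxic genes (-1.12, up to -0.337) and adipocytes (-2.87, up to -1.43).

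With the ages of the FIP cats by description number, the age covariate ended the list calls of FIP against non-FIP for adipocytes (-1.62, adjusted p = 0.055), mesothelium (2.81, adjusted p = 0.082), regulatory T cell and checkpoint genes (0.88, adjusted p = 0.073) and ribosomal proteins (-0.304, adjusted p = 0.082). The call of regulatory T cell and checkpoint genes was also lost in cats aged at most 4 years by these ages (1.18, adjusted p = 0.057).

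Some directions turned. APOL6 against FCoV-negative cats (-5.32) was 0.319 in the deeper libraries, 0.137 without the 3 libraries with high fat RNA and 0.14 without FCoV-negative cat 1.

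The other turns were in FCoV-positive against FCoV-negative cats. In the deeper libraries LTF was 0.319, S100A8 0.185, PGLYRP1 0.0906 and the neutrophil median 0.185. In cats aged at most 4 years CCL5 was -0.129, UPK1B -0.851, LRRN4 -0.0445, and the medians were 0.132 for T cell markers, 0.378 for germinal centre genes and -0.188 for cytotoxic genes. In the shallower libraries UPK1B was -0.237, LRRN4 -0.718, WT1 -0.176 and UPK3B -1.74, and the medians were 0.139 for T cell markers, 0.531 for germinal centre genes (past the threshold, adjusted p = 0.018), -0.218 for fibroblast genes and -0.262 for mesothelial markers. Without the cats with neoplasia the T cell median was 0.0528, and it reached 0.0631 with 1 library omitted.

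Apart from these, over all alternatives other than the omission of single libraries, 3339 gene values kept direction and side of the threshold, 310 kept direction and lost the threshold and 57 kept direction and gained it, while for list tests 560 kept both and 97 lost the threshold. In the single depth classes, depth and the number of cats were not separated.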

Other observations

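The Gene Ontology tests of this part were chosen after the results had been seen. Genes of the endoplasmic reticulum stress response rose in FIP against non-FIP nodes: 26 of 33 genes with that term in the authors' tables were called higher (edgeR), against 1329 of 4260 genes with any term (31.2 percent). The hypergeometric test takes genes, not cats, as units, so its p-values can be too small. It gave an adjusted p = 1.5e-06 over 541 terms of 10 to 500 genes, and 1.4e-05 over a wider set of 8790 terms. The transcription factor DDIT3 rose by 1.99 ± 0.26 (log2, SE), SEL1L by 1.73 ± 0.23 and the stress sensor ERN1 by 2.13 ± 0.38. Genes of degradation at the endoplasmic reticulum were higher in 22 of 29 (adjusted p = 4e-05, wider set 0.00044), with DNAJB9 up by 1.91 ± 0.30 and SELENOS by 1.91 ± 0.30. Protein folding genes were higher in 20 of 28 (adjusted p = 0.00045, wider set 0.0052) and genes of transport from the endoplasmic reticulum to the Golgi in 18 of 24 (adjusted p = 0.00044, wider set 0.0051). Some members, TXNDC5 among them, also belong to the plasma cell list. The background is made of genes listed from these same samples, and DDIT3, SEL1L, ERN1, DNAJB9 and SELENOS were picked after their values had been seen.

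Antiviral defence genes were higher in 32 of 38 (adjusted p = 5.3e-09, wider set 3.9e-08) and innate immune genes in 60 of 93 (adjusted p = 5.3e-09, wider set 3.9e-08). DNA repair genes were lower in 29 of 53 (adjusted p = 0.024), which did not pass over the wider set of terms (adjusted p = 0.29).

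The 10 most abundant genes of each library took 22.4 ± 8.64 percent of counts in 10 FIP cats, 9.36 ± 1.71 percent in 8 FCoV-negative cats and 10.2 ± 6.13 percent in 6 FCoV-positive cats (mean ± SD).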
